A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

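Chromatin immunoprecipitates with antibodies against Flag, Myc and acetylated H4, and the input DNA, were hybridised to 18 Agilent tiling arrays, 3 biological replicates for each antibody in WT and in SET2 deletion cells, per the labels. Per the labels' protocols, cells grown in 2% raffinose at 25 °C were held in alpha factor for 4 h, moved to 2% galactose for 45 min and cross-linked with 1% formaldehyde for 15 min. The lysates were used for all the antibodies, and DNA was amplified by in vitro transcription before labelling. On every array the immunoprecipitate was labelled with Cy5 (red) and the input with Cy3 (green), per the labels, so no dye swap balances a dye bias. The labels give 1 strain name for both strains. Groups and replicate numbers were taken from the sample titles.

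The deposited scanner files hold spot intensities in both channels from Agilent Feature Extraction 10.5.1.1, per the file headers. The processed intensities are background-subtracted and linearly dye-normalized, per the file headers, and dye normalization sets the channels of an array level with each other, so an overall gain or loss of an immunoprecipitate cannot be seen. The deposited series matrix holds log2 ratios of the same arrays. Its 18 columns equalled log2 of processed red over green of a scanner file to within 2.4e-06, uncentred, with medians from −0.30 to 0.07. In 5 columns the replicate number differed from that of the matching scanner file, always within the same group. Which number is right is not given in the sources used here, and the numbers of the scanner files were used. This bears on left-out replicates, pairing and the cultures of the ratio: with the numbers of the series matrix the pooled SD of the low-minus-high ratio was 0.0687 in place of 0.0388, at the same difference, and all 16 named ratio windows still had one sign in all 9 comparisons. The aligner or annotation behind the probe positions is not given in the sources used here. The headers name the sacCer1 build, and positions are given in it.

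Each array held 45219 spots. After 3444 control spots were left out, 41775 probes stayed, of a median length of 60 bases, 41480 nuclear and 295 mitochondrial. The value of a probe was log2 of processed red over processed green, minus the array's median over non-control probes. Saturated spots were kept. The gene table given covers the R64 assembly, and coordinates were not carried between builds, so the tests planned on genes, promoters, positions within genes, gene lists, gene length and region classes could not be made. Only the same contrasts, the set of windows near chromosome ends and the correlation of changes were carried over, on windows of 1000 bp with at least 2 nuclear probes (11378 windows, median 4 probes), a choice made after the files were seen. FLO8, STE11 and PCA1, which were to be named in any case, are not located for the same reason. The gene table was used only for the coding length, name and neighbours of SET2.

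Window means of the 18 arrays were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 6 groups, which share 1 estimate of the spread (12 residual degrees of freedom). The contrasts were Flag minus Myc in the SET2 deletion strain minus the same in WT, and the strain difference in each antibody. A window was called at a Benjamini-Hochberg adjusted p under 0.05, within each contrast. Windows are named by the rule set before the data were examined, applied to windows in place of genes: the 8 largest rises and 8 largest falls in the ratio and in acetylated H4, and 4 and 4 in Flag and Myc, among called windows in which all 9 comparisons of a WT with a deletion culture have one sign. Arrays of the same strain and number were taken as 1 culture for the ratio. Neighbouring windows share DNA fragments and are not independent.

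Per-array summaries compared the lowest and highest of 5 equal groups of windows by WT new-over-old ratio or WT acetylated H4, and windows within 10 kb of the outermost probe with windows over 50 kb away. They were compared between strains by exact two-sided permutation tests, whose smallest p is 0.1 with 3 against 3. These summaries were chosen after exploring the data, and the windows were grouped by other arrays than those compared, although the arrays may share cultures. The list of windows within 20 kb of an end was tested in the 4 contrasts with camera (preset correlation 0.01, and an estimated one of 0.0308) and fry, and adjusted over the 4 contrasts. Fry's p for movement on balance one way was adjusted likewise.

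Arrays with the same scan stamp (date and time) in the headers were taken as 1 scan batch, which gave 6 batches. Whether batches were scanned on different days was not examined. SET2 deletion Flag arrays lay in batches 1 and 2 and WT Flag arrays in batch 3. Batch 4 held 2 Myc arrays of each strain. Batch 5 held Myc array 3 of each strain and 2 WT acetylated H4 arrays. Batch 6 held WT array 3 and all SET2 deletion acetylated H4 arrays. Scan batch was fitted as a block for Myc and acetylated H4 and as a random block (consensus correlation 0.054) in all contrasts. Same-numbered WT and SET2 deletion Flag arrays deviated together from their group means (r = 0.29, 0.18 and 0.15), so replicate numbers may pair the Flag arrays. With 3 arrays per group such a match can also arise by chance, which was not tested. No label states that same-numbered arrays share a day.

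The alternatives were no centring, scaling by the median absolute deviation, normexp (offset 50) on the median and background signals (the files used hold no mean signals), loess, quantile normalization within an antibody, the series matrix, filters on dim probes, window sizes and probe minimums, medians over probes, fits of only the arrays compared, blocks, and leaving out each replicate. Mitochondrial DNA carries no nucleosomes, so mitochondrial probes gave a background: each array's median linear mitochondrial ratio was subtracted, with a floor of 0.05 of the median. The fit was tested on simulated data with 200 of 11378 windows changed. It recovered 5% of changes of 0.5 log2 and 60% of changes of 1 log2 for the ratio. For Flag it recovered 28% and 96%, and for acetylated H4 22% and 98%. Calls among unchanged windows were 3, 10 and 5. In the data 7.3%, 11.8% and 47.3% of windows were called in these contrasts. The Benjamini-Hochberg cut-off depends on this share, so recovery in the data can differ from the simulated values. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R data.table, version 1.17.8.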

Results

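Replacement of histone H3 and acetylation of histone H4 were profiled by chromatin immunoprecipitation on tiling arrays in budding yeast with SET2 (WT) and with SET2 deleted. Set2 methylates lysine 36 of histone H3 on transcribed genes. The cells carried an exchange system, in which Flag and Myc are epitopes on 2 forms of histone H3. As the study is known, Flag marks H3 made after galactose is added (new H3) and Myc marks H3 present before (old H3), so the Flag over Myc ratio follows the entry of new H3 into chromatin. Cells were grown in 2% raffinose at 25 °C, arrested with alpha factor for 4 h, given 2% galactose for 45 min, and fixed. DNA was recovered with antibodies against Flag, Myc and acetylated H4, and each was hybridised against its input DNA on a 2-colour array.

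The 18 arrays formed 6 groups (2 strains and 3 antibodies) of 3 biological replicates. Each array held 41775 probes, 41480 of them on the 16 nuclear chromosomes, with a median spacing of 257 bp. The median processed intensity of a probe lay between 799 and 1337 in the input channel and between 751 and 1246 in the immunoprecipitate channel. On the WT Flag arrays 58.4%, 95.0% and 87.0% of probes were well above background in the immunoprecipitate channel, array 1 being the dimmest of all. The SET2 deletion Flag arrays had at least 99.7%. WT acetylated H4 arrays had 87.4%, 99.4% and 89.7%, against at least 96.4% on those of the deletion strain. All values below are log2 immunoprecipitate over input, centred on each array's median and averaged in 11378 windows of 1000 bp in the coordinates of the sacCer1 build. Genes were not assigned to windows, because no annotation of that build was used here. Replicate arrays correlated across windows with r from 0.847 to 0.984. The number of arrays limits the precision of each value.

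The input channel showed the SET2 deletion directly. On chromosome 10, 8 neighbouring probes from 102375 to 104454, a span of 2080 bp, lost their input signal on all 9 SET2 deletion arrays and kept it on all 9 WT arrays. Their median log2 input was −6.86 ± 1.17 (SD over 9 arrays) against 0.06 ± 0.06 (SD over 9 arrays) in WT, a difference of −6.92. The probes were found by this gap, so the separation of the strains follows from the choice of probes, and the 9 arrays of a strain are taken as 3 cultures here. This was the only run of 2 or more probes with a gap of over 2 log2 between the strains, and 2 single probes on chromosome 12 (starting at 179392 and 382237) met the same criterion. In the R64 assembly's table SET2 (YJL168C), of 2202 bp coding length, lies between ASG7 and ERG20 on chromosome X. In the window 103001 to 104000 of chromosome 10 all 4 probes lost their input, so its rises in the ratio (3.63), Flag (3.03) and acetylated H4 (2.93) without SET2 are no measure of chromatin. In the window 104001 to 105000 (10_104001) 2 of the 4 probes lost their input, and the ratio rose by 2.50 and Flag by 1.96. With input well above background on all arrays the ratio rise there was 2.15 (limma adjusted p = 8.63e-07), but with normexp background correction it was 1.02 (limma adjusted p = 0.0840) and with loess within arrays 0.75 (0.0567). With normexp background correction the Flag rise there was 0.44 (limma adjusted p = 0.216).

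In WT cells the ratio of new over old H3 differed widely along the genome. The median window was at −0.08, the 10th percentile at −1.15, the 90th at 2.37 and the 99th at 5.31, while the median SD between the 3 cultures in a window was 0.20. The highest ratios were measured on chromosome 14 at 704001 to 705000 (8.22 ± 0.33, SD, n = 3), on chromosome 7 at 785001 to 786000 (8.21 ± 0.37), on chromosome 14 at 576001 to 577000 (7.99 ± 0.69) and on chromosome 16 at 433001 to 434000 (7.82 ± 0.05). In these windows Flag was enriched by 5.30 to 6.44 and Myc stood at −2.91 to −1.55. The lowest ratios lay on chromosome 3 at 2001 to 3000 (−2.74 ± 1.19), on chromosome 7 at 1001 to 2000 (−2.57 ± 0.26), on chromosome 3 at 3001 to 4000 (−2.55 ± 0.48) and on chromosome 6 at 259001 to 260000 (−2.52 ± 0.53). The landscape was largely shared by the strains: WT and SET2 deletion means correlated across windows with r = 0.959 for Flag, 0.937 for Myc and 0.786 for acetylated H4. These 8 windows were chosen after their values were seen.

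Acetylated H4 was the measurement that differed most between the strains. It changed in 5379 of 11378 windows (limma, Benjamini-Hochberg adjusted p under 0.05), being higher without SET2 in 2124 and lower in 3255, with median changes of 0.64 and −0.60. The surplus of falls depended on the scaling, with 2530 higher and 2696 lower without centring, 2715 and 2970 with quantile normalization, and 2121 and 2440 after mitochondrial subtraction, while loess gave 3194 windows, 1171 higher and 2023 lower. Centring on mitochondrial probes left 1 window called, that of SET2 on chromosome 10. The largest rise outside the SET2 locus was on chromosome 8 at 434001 to 435000, from −1.61 ± 0.59 in WT to 0.34 (change 1.95 ± 0.20 SE, limma adjusted p = 1.58e-06). Similar rises were found on chromosome 7 at 509001 to 510000 (1.82), chromosome 10 at 494001 to 495000 (1.79), chromosome 3 at 20001 to 21000 (1.78), chromosome 6 at 35001 to 36000 (1.68), chromosome 15 at 963001 to 964000 (1.56) and chromosome 9 at 390001 to 391000 (1.56). WT acetylated H4 in these 7 windows lay between −1.61 and −0.32, and the WT new-over-old ratio between −2.28 and −0.43. The new-over-old ratio rose together with acetylated H4 in 2 of them, on chromosome 6 (1.05, adjusted p = 0.00976) and chromosome 15 (1.42, adjusted p = 0.00123).

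Of the 8 windows with the largest falls in acetylated H4, 6 lay between 296001 and 314000 on chromosome 3, with changes from −1.64 to −2.15. The other 2 were at the left end of chromosome 3 (2001 to 3000, −1.78) and on chromosome 11 at 176001 to 177000 (−1.66). Adjacent windows that fell formed 42 runs of 5 windows or more, against 9 such runs of rises. With scan batch as a block, however, there were 7 of each. The longest run of falls covered 16 windows on chromosome 3 from 289001 to 305000. With scan batch as a block 15 of these were called lower, and the longest run was 9 windows. Within the scan batch that held both strains their mean change was −1.18, against −1.24 in the main fit. The next longest runs of falls were 11 windows on chromosome 5 from 559001 to 570000 (mean change −0.78) and 10 windows on chromosome 15 from 1001 to 11000 (−0.73). With scan batch as a block 3887 windows were called, 1962 higher and 1925 lower. Within the 1 scan batch that held both strains (1 WT and 3 SET2 deletion arrays) the median change of all windows was −0.07, against −0.11 over all arrays. These 2 fits estimate the change against the same single WT array, and the within-batch fit takes its spread from the 3 deletion arrays. With scan batch as a random block 5249 windows were called, 2109 higher and 3140 lower.

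The change in acetylated H4 differed with the WT level of H3 exchange. In the 2276 windows with the lowest WT new-over-old ratio, acetylated H4 went from −0.35 ± 0.12 (SD, n = 3) in WT to −0.15 ± 0.03, with 878 windows higher and 370 lower. In the 2276 windows with the highest WT ratio it went from 0.17 ± 0.03 to −0.14 ± 0.03, with 75 windows higher and 975 lower. The low-ratio windows thus stood below the high-ratio windows in WT (−0.52 ± 0.09) and level with them without SET2 (−0.01 ± 0.02), a difference between strains of 0.51. Every SET2 deletion array lay above every WT array, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Within the scan batch that held both strains the difference was 0.59, and after loess it was 0.27. Across windows the change in acetylated H4 correlated with the WT ratio (Pearson's r = −0.31) and with WT acetylated H4 (r = −0.34), whose arrays also enter the change.

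**Figure D1:**
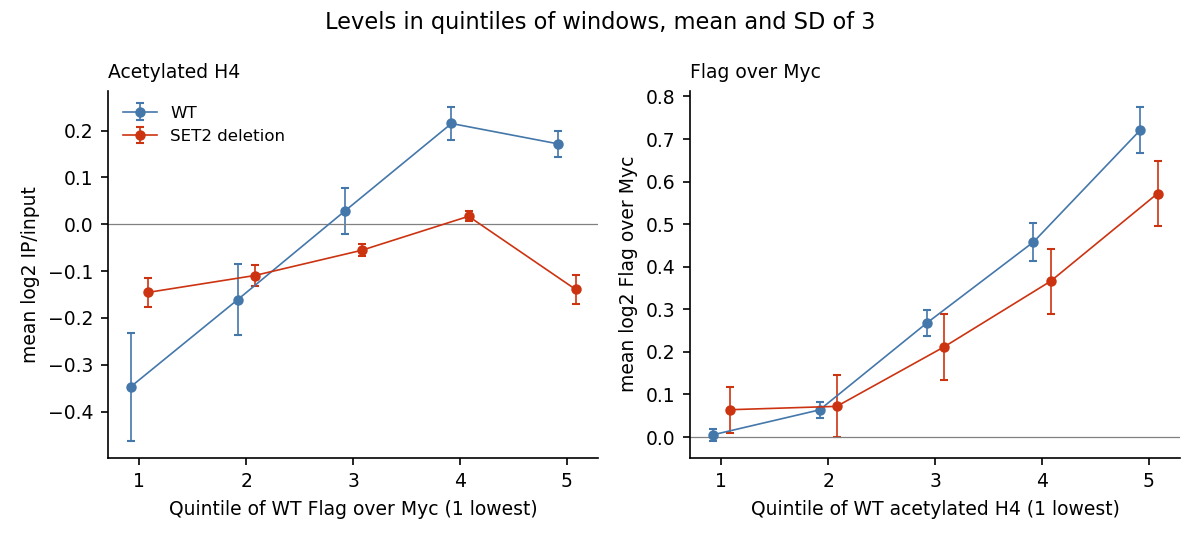
Left, mean log2 acetylated H4 over input in quintiles of windows by WT Flag over Myc; right, mean log2 Flag over Myc in quintiles by WT acetylated H4. Points are means of 3 arrays (left) or 3 pairs of arrays (right) and bars are SD. Acetylated H4 rises from −0.35 to 0.17 between the outer quintiles in WT and is at −0.15 and −0.14 in the SET2 deletion strain.

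Acetylated H4 was also lower near chromosome ends without SET2. In the 96 windows within 5 kb of a chromosome's outermost probe it was −0.68 ± 0.15 (SD, n = 3) in WT and −1.35 ± 0.04 in the deletion strain, and 61 windows fell while 0 rose (limma). Between 5 and 10 kb the means were −0.14 ± 0.06 and −0.52 ± 0.02, and between 10 and 20 kb 0.07 ± 0.05 and −0.17 ± 0.01. Over 50 kb from an end they were −0.01 ± 0.05 and −0.06 ± 0.02. Of the 32 chromosome ends, taken as 20 kb each, 31 had a lower mean in the deletion strain, the left end of chromosome 14 (0.01) being the exception, and the ends held as few as 2 windows. The left ends of chromosomes 2 (−0.03) and 13 (−0.03) and the right end of chromosome 11 (−0.05) fell no more than the windows over 50 kb away (−0.05). Mean new H3 was also lower there, Flag within 5 kb of an end being −0.14 ± 0.08 in WT and −0.37 ± 0.07 without SET2. Only 9 of these 96 windows were called lower in Flag, and 2 higher. Myc was 0.14 ± 0.03 in WT and 0.20 ± 0.04 without SET2.

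The windows within 20 kb of an end had been set as a list before the data were examined, as genes near ends, and the list held 485 windows here. In acetylated H4, 225 fell and 45 rose, or 236 and 45 adjusted over the list alone, and the list ranked lower than other windows (camera, adjusted p = 2.96e-05; adjusted p = 0.0738 with an estimated correlation). In Flag 48 fell and 26 rose, or 61 and 31 adjusted over the list alone (camera, adjusted p = 0.0105; adjusted p = 0.18 with an estimated correlation). In the new-over-old ratio 37 fell and 14 rose, or 46 and 17 adjusted over the list alone (camera, adjusted p = 0.0111; adjusted p = 0.18 with an estimated correlation). In Myc 3 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera, adjusted p = 0.31). No camera call of the list thus held with an estimated correlation. Fry, which asks whether the list moved on balance one way, gave adjusted p of 8.39e-07 for acetylated H4 and 0.00779 for the ratio. For Flag fry gave 0.0243 and for Myc 0.0416. Fry does not compare the list with other windows, which also moved. The median change in acetylated H4 was −0.38 in the list and −0.10 in other windows. In the ratio these medians were −0.19 and −0.05, in Flag −0.11 and 0.01, and in Myc 0.05 and 0.04. With scan batch as a block camera gave acetylated H4 an adjusted p of 0.000129, adjusted over Myc and acetylated H4 only. The end-minus-interior difference between strains in acetylated H4 was −0.46 over all arrays and −0.27 after loess. Within the scan batch that held both strains it was −0.42.

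**Figure D2:**
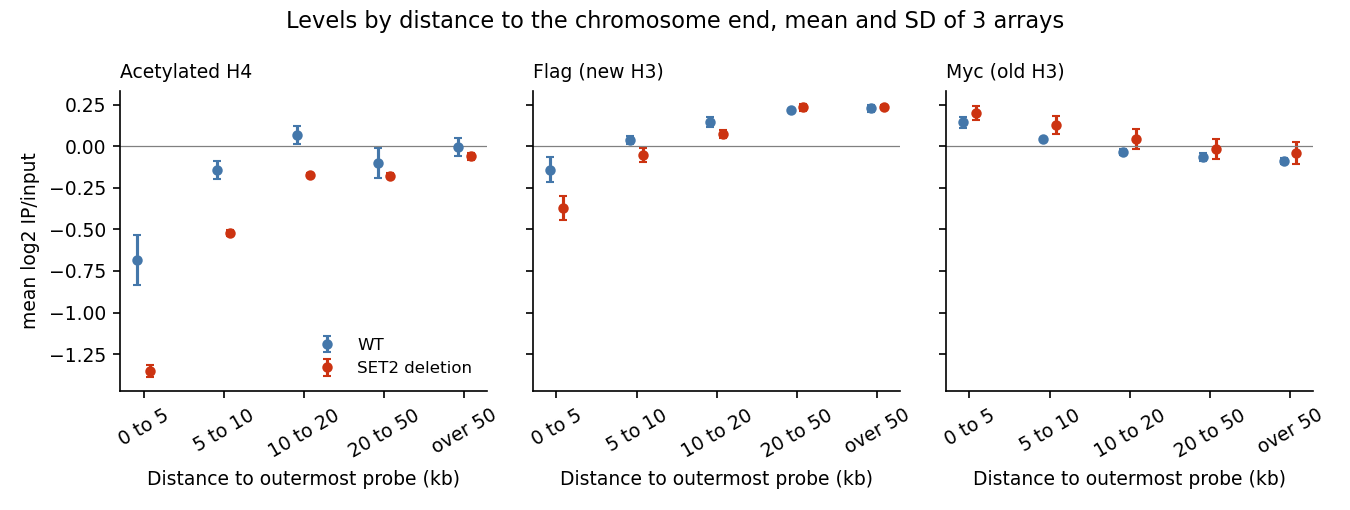
Mean log2 immunoprecipitate over input of windows by distance to the outermost probe of the chromosome, for acetylated H4, Flag and Myc. Points are means of 3 arrays and bars are SD. Within 5 kb acetylated H4 is −0.68 in WT and −1.35 in the SET2 deletion strain, while over 50 kb from an end it is −0.01 and −0.06.

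The right end of chromosome 3 stood apart from the other ends. Its last 20 kb had mean acetylated H4 of −0.49 ± 0.15 (SD, n = 3) in WT and −2.01 ± 0.17 in the deletion strain, a change of −1.52, where the next largest change of an end was −0.70. In the 16 windows from 289001 to 305000, Flag went from −0.50 ± 0.06 to −1.09 ± 0.12 and Myc from 0.14 ± 0.03 to 0.30 ± 0.08. The strongest single change in the ratio outside SET2 was here: at 299001 to 300000 new over old H3 went from 2.21 ± 0.25 to −0.46 (change −2.68 ± 0.20 SE, limma adjusted p = 5.87e-08), with Flag at −1.95, Myc at 0.73 (adjusted p = 0.0266) and acetylated H4 at −1.52. In the next window, 300001 to 301000, the ratio changed by −1.56. Without the right end of chromosome 3 the mean change of the other ends in acetylated H4 was −0.33. The run was chosen after its values were seen.

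**Figure D3:**
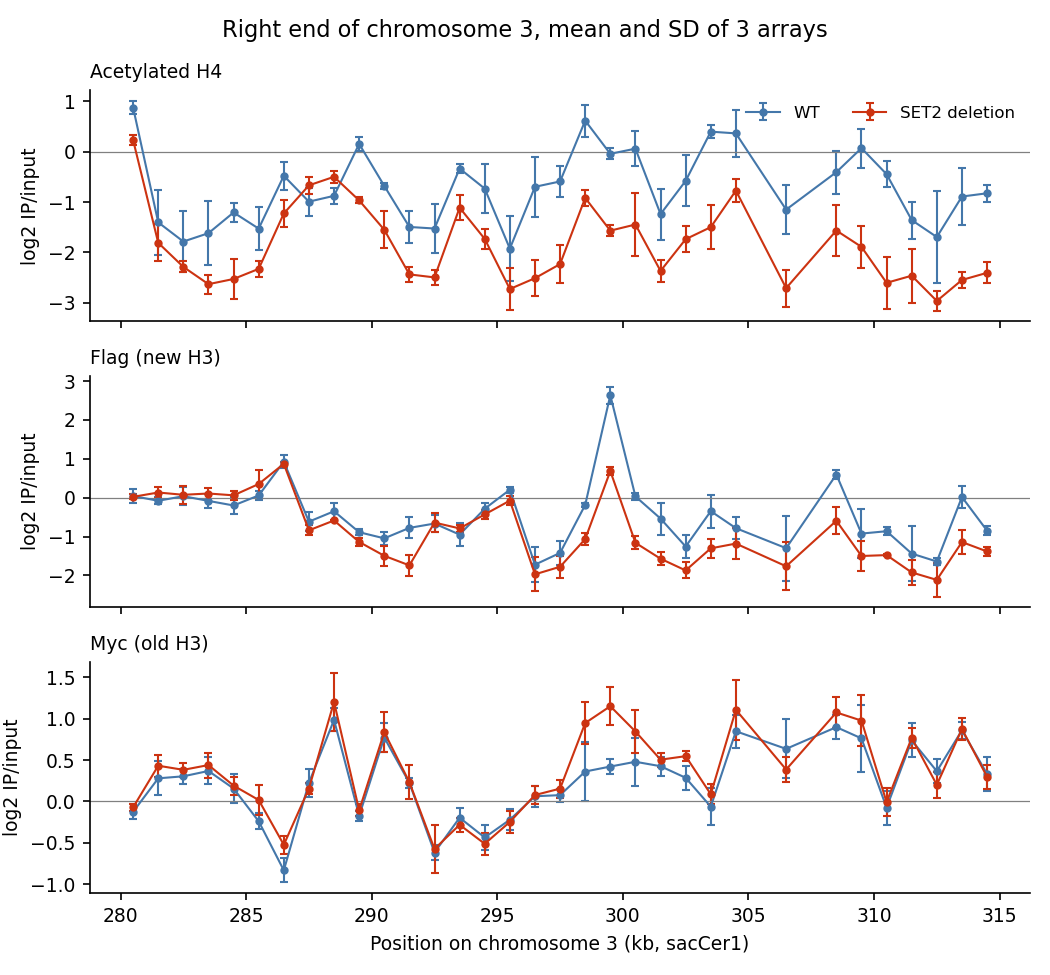
Mean log2 immunoprecipitate over input in 1000 bp windows at the right end of chromosome 3 (sacCer1 position in kb) for acetylated H4, Flag and Myc in both strains. Points are means of 3 arrays and bars are SD. From 289001 to 305000 mean acetylated H4 is −0.52 in WT and −1.75 in the SET2 deletion strain, and mean Flag is −0.50 and −1.09.

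The new-over-old H3 ratio, the readout of exchange, changed in fewer windows than acetylated H4. It differed in 825 of 11378 windows (limma, adjusted p under 0.05), 364 higher and 461 lower without SET2, with median changes of 0.84 and −0.82. Among the rises Flag was also called higher in 317 of the 364 windows, and Myc lower in 4. Of the 461 windows that fell, 290 were called lower in Flag and 9 higher in Myc. The median changes were 0.67 in Flag and −0.21 in Myc among the rises, and −0.51 and 0.32 among the falls. As the windows were called on Flag minus Myc, their choice itself pushes Flag with the ratio and Myc against it. Over all 11378 windows, called or not, all 9 comparisons of a WT with a deletion culture had one sign in 33.2%, where exchangeable cultures would give 10% on average. Windows are not independent, and the Flag arrays of the strains lay in different scan batches. This share thus does not part strain from scan batch.

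The strongest rise outside the SET2 locus was on chromosome 16. In the 5 windows from 398001 to 403000 the ratio went from −0.17 ± 0.05 (SD, n = 3) to 1.20 ± 0.14, and in 401001 to 402000 it rose by 2.14 ± 0.21 SE (limma adjusted p = 9.34e-06). On chromosome 10, the 6 windows from 364001 to 370000 went from 0.33 ± 0.12 to 1.26 ± 0.05, with a rise of 1.63 in 366001 to 367000. On chromosome 6, the 6 windows from 66001 to 72000 went from 0.75 ± 0.07 to 1.70 ± 0.14. Other rises were on chromosome 2 at 654001 to 655000 (1.71), chromosome 11 at 474001 to 475000 (1.55) and chromosome 13 at 250001 to 251000 (1.54), and on chromosome 16 at 402001 to 403000 (1.54). Falls outside chromosome 3 included a run of 8 windows on chromosome 10 from 604001 to 612000, from 2.80 ± 0.12 to 1.86 ± 0.21. Single windows fell on chromosome 15 at 1071001 to 1072000 (−1.93), chromosome 1 at 189001 to 190000 (−1.85), chromosome 11 at 382001 to 383000 (−1.75), chromosome 16 at 454001 to 455000 (−1.61) and chromosome 7 at 1011001 to 1012000 (−1.51). On chromosome 16 from 445001 to 450000 the ratio fell from 1.95 ± 0.10 to 0.63 ± 0.14, with a change of −1.59 in 446001 to 447000, while acetylated H4 went from −0.95 ± 0.32 to −0.41 ± 0.07. The runs were chosen after their values were seen.

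Centring on mitochondrial probes, which left 1 window called in the ratio, ended the calls of all 8 named falls and of 7 of the 8 named rises. It moved the changes of all windows up alike: these 7 rises grew from between 1.54 and 2.50 to between 2.62 and 3.57, and the falls shrank from between −2.68 and −1.51 to between −1.60 and −0.43. The calls of the rises ended because the SE grew, from between 0.17 and 0.34 to 0.88 in each of them. The calls of 3 named falls were also lost under other processing. With loess within arrays window 15_1071001 was −0.71 (limma adjusted p = 0.171), window 11_382001 was −0.95 (0.0886) and window 7_1011001 was −0.56 (0.107). With normexp background correction window 11_382001 was −0.95 (limma adjusted p = 0.0843) and window 7_1011001 was −0.77 (0.131). After mitochondrial subtraction window 15_1071001 was −1.80 ± 0.76 SE (limma adjusted p = 0.137), against −1.93 ± 0.33 in the main fit, so its call ended mostly by a larger SE, and window 7_1011001 was −1.16 ± 0.40 SE (0.0669), against −1.51 ± 0.30.

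The 3 SET2 deletion Flag arrays lay in other scan batches than the 3 WT Flag arrays. No block can thus part scan batch from strain in the ratio. With scan batch as a random block 735 windows were called, 324 higher and 411 lower. Leaving out SET2 deletion replicate 1, 2 or 3 left 193, 284 or 232 windows, and leaving out WT replicate 2 left 479. Loess gave 411 windows and the median over probes 490, while subtracting the mitochondrial background gave 1329, 372 higher and 957 lower. Which direction held more windows depended on the processing, with 731 higher and 213 lower without centring, 655 and 499 with quantile normalization, and 254 and 157 with loess.

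New H3 alone (Flag) changed in 1343 windows, 722 higher and 621 lower, and old H3 alone (Myc) in 16 windows, 12 higher and 4 lower (limma, adjusted p under 0.05). The largest Flag rises outside SET2 were on chromosome 2 at 211001 to 212000 (1.44) and chromosome 16 at 401001 to 402000 (1.44). The largest falls were on chromosome 3 at 299001 to 300000 (−1.95), chromosome 16 at 446001 to 447000 (−1.55) and 447001 to 448000 (−1.45), and chromosome 15 at 1071001 to 1072000 (−1.44). In Myc the largest rises were on chromosome 11 at 382001 to 383000 (1.15), chromosome 10 at 195001 to 196000 (1.13), chromosome 13 at 26001 to 27000 (0.96) and chromosome 4 at 1128001 to 1129000 (0.94), and WT Myc there lay between −3.02 and −0.65. Myc fell on chromosome 6 at 66001 to 67000 (−0.88), chromosome 15 at 131001 to 132000 (−0.74), chromosome 11 at 474001 to 475000 (−0.66) and chromosome 12 at 1048001 to 1049000 (−0.64), and the new-over-old ratio rose in each of these 4 windows (1.04 to 1.55). At an unadjusted limma p under 0.05, Myc differed in 1284 windows.

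For Flag the random scan block, which cannot part scan batch from strain there either, gave 1063 windows. Without SET2 deletion replicate 1, 2 or 3, 538, 519 or 639 Flag windows were left. Higher Flag calls outnumbered lower ones without centring (1515 and 303), after scaling by the median absolute deviation (405 and 177) and with normexp (1537 and 812). The reverse held after mitochondrial subtraction (822 and 1915) and with both channels well above background (279 and 529), where 7096 windows were tested. The Flag call of window 15_1071001 was lost with loess within arrays (−0.41, limma adjusted p = 0.176) and after mitochondrial subtraction (−1.31 ± 0.54 SE against −1.44 ± 0.23, limma adjusted p = 0.0839), and that of window 2_211001 without set2 replicate 2 (1.04, limma adjusted p = 0.0722). For Myc the scan block gave 16 windows and the scan batch with 2 arrays of each strain 10. Leaving out any 1 replicate left 0 to 10. Dividing each array by its median absolute deviation gave 940, 704 higher and 236 lower. A fit of only the Myc arrays called 0 windows, so none of the named Myc calls held there. The changes were those of the main fit, with SE from 0.10 to 0.24 (0.11 to 0.20 in the main fit) and limma adjusted p from 0.0644 to 0.185, and this fit has fewer residual degrees of freedom. With the median over probes window 13_26001 was 0.42 (limma adjusted p = 0.604) and window 4_1128001 was 0.35 (0.625). The 4 named Myc falls stood at −0.86 to −0.58 there and lost their calls too (limma adjusted p from 0.0542 to 0.184). Window 6_66001 was −0.39 with normexp (limma adjusted p = 0.430), −0.38 with loess (0.494) and −0.46 with both channels well above background (0.145). Window 12_1048001 was −0.24 with loess (limma adjusted p = 0.522).

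Changes in H3 exchange and in acetylated H4 tended to run the same way. Of the 364 windows with a higher ratio, 173 had higher acetylated H4 and 28 lower, where independent lists of these sizes would share 68.0 and 104. Of the 461 windows with a lower ratio, 222 had lower acetylated H4 and 22 higher, where independent lists would share 132 and 86.1. Across all windows, which are not independent replicates, the changes correlated with Pearson's r = 0.33 and Spearman's rho = 0.33, and with Flag in place of the ratio r was 0.36. Pearson's r was 0.18 after scaling by the median absolute deviation, 0.21 after mitochondrial subtraction, and 0.24 both with normexp and with both channels well above background. The other 9 splits of the 6 cultures gave r from −0.04 to 0.39, so a correlation of this size also arose between mixed groups. The covariance was 0.0697 in the real split and at most 0.0231 in the others. Each other split has cultures of both strains on both sides, which shrinks any difference between strains or scan batches without removing it. A lower covariance there thus follows from the design, and no conclusion is drawn from it.

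The ratio change was set against WT acetylated H4 in the same way. In the 2276 windows with the lowest WT acetylated H4 the ratio was 0.01 ± 0.01 (SD, n = 3) in WT and 0.06 ± 0.05 without SET2, and in the 2276 with the highest it was 0.72 ± 0.05 and 0.57 ± 0.08. The low-minus-high difference went from −0.72 ± 0.05 to −0.51 ± 0.02 (exact two-sided permutation test, p = 0.1, the smallest possible). With the main processing this change came from Flag, whose low-minus-high difference changed by 0.22, and not measurably from Myc (0.01, exact two-sided permutation test, p = 0.8). The difference between strains in the ratio, 0.21, was 0.02 after loess, 0.06 after normexp, 0.09 after scaling by the median absolute deviation and 0.15 after quantile normalization. In Flag it was 0.06, 0.10, 0.16 and 0.18 with the same settings. The ratio thus changed by less than Flag in each of them, the gap being the change in Myc.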

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

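The patterns in this part and the tests of them were chosen after the data were seen, and those of old and new H3 near chromosome ends, of the spread of the arrays in the ratio and Flag, and of the splits of the cultures after the results they bear on were seen.

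Mitochondrial probes, which lie in no window, gave higher ratios in all 3 SET2 deletion arrays than in all 3 WT arrays for Flag and for Myc. The Flag mean was −2.48 ± 0.22 (SD, n = 3) in WT and −1.48 ± 0.48 without SET2, a difference of 1.00, and the Myc mean was −7.03 ± 0.42 and −4.95 ± 0.77, a difference of 2.08 (exact two-sided permutation test, p = 0.1 for each, the smallest possible). Acetylated H4 differed by −0.16 (exact two-sided permutation test, p = 0.9). No group of 9 input values held a sample far from the others, and groups of 3 were not tested for one.

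Acetylated H4 rose without SET2 where the WT new-over-old ratio was low and fell where it was high, by a low-minus-high difference of 0.51 between strains (pooled SD 0.07). A higher background on some arrays is argued against, since the difference was 0.65 (pooled SD 0.07) after the mitochondrial background was subtracted. A wider spread of log ratios in 1 strain is argued against by 0.48 (pooled SD 0.02) after scaling by the median absolute deviation, and an input difference by 0.65 (pooled SD 0.08) in the immunoprecipitate channel alone. Loess lowered the difference to 0.27. The loss of Set2 may account for it but stays a hypothesis. The reason is that 2 of the 3 WT arrays lay in another scan batch than the deletion arrays. The value within a scan batch, 0.59, rests on 1 WT array.

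Acetylated H4 near chromosome ends was lower without SET2, by an end-minus-interior difference of −0.46 (pooled SD 0.03), which loess moved to −0.27 (pooled SD 0.11). Windows with input within 0.5 log2 of the array median gave −0.44 (pooled SD 0.03). Cross-hybridisation of repeated end sequences stays open all the same, since input signal does not tell repeated from unique sequences. The probes of the SET2 run alone had mean log2 input from −1.35 to 1.95 in WT. A loss of old H3 there is argued against by Myc, which differed by 0.0230 (pooled SD 0.02), but new H3 (Flag) differed by −0.16 (pooled SD 0.05) and total H3 was not measured, so less H3 near ends stays open. An input difference is argued against by −0.47 (pooled SD 0.05) in the immunoprecipitate channel alone. A spread of silent chromatin from the ends without Set2 is a possible explanation that was not tested, and a difference in the end sequences of the 2 strains also stays open.

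The new-over-old ratio rose without SET2 where WT acetylated H4 was low relative to where it was high, by 0.21 (pooled SD 0.04). Dim signals on the WT Flag arrays stay open. Probes well above background in both channels of all arrays gave 0.18 (pooled SD 0.02), but normexp background correction gave 0.06 (pooled SD 0.04). A higher background stays open, as its subtraction gave 0.14 with a pooled SD of 0.07. Scan batch cannot be told apart from strain for Flag. There the scan batches of the deletion strain differed by −0.0429, with 1 array in one of them. In Flag, where the difference was 0.22 (pooled SD 0.04), a wider spread of the arrays of 1 strain is argued against as the whole cause by 0.16 (pooled SD 0.02) after scaling by the median absolute deviation and 0.18 (pooled SD 0.02) after quantile normalization. In the ratio a wider spread of the arrays stays open, since scaling left 0.09 (pooled SD 0.08) and quantile normalization 0.15 (pooled SD 0.05). Loess left 0.02 (pooled SD 0.08) in the ratio and 0.06 (pooled SD 0.04) in Flag, so a trend of the log ratios with signal intensity also stays open.

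The 6 cultures can be split in only 10 ways, too few for a share under 0.05. As many windows as in the real split were given by 1 of the 10 splits, the real one, in each comparison. The real counts were 825 for the ratio, 1343 for Flag, 16 for Myc and 5379 for acetylated H4. The highest of the other splits were 0, 3, 0 and 0. Each other split has cultures of both strains on both sides, which shrinks any difference between strains or scan batches and adds it to the spread. Fewer calls there thus follow from the design and do not part strain from scan batch.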

How the results depend on the processing

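Windows of 0.5 and 2 kb, the mitochondrial settings and the filter on both channels were chosen after seeing the data. So were fits within a scan batch and all alternatives for the per-array summaries. Tests on genes, promoters, positions within genes, gene lists, gene length and region classes, and centring on probes outside genes and promoters, were not run, as no annotation of the build was used. The Flag ratios are limited by scan batch, which cannot be told apart from strain. They are also limited by dim signals, with 58.4% of probes well above background on WT Flag array 1.

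The ratio count of 825 windows (364 higher, 461 lower) was 411 with loess (254 and 157), 490 with medians over probes, 1329 after subtraction of the mitochondrial background (372 and 957) and 1 with centring on mitochondrial probes. Leaving out a replicate gave 193 to 623, with 479 without WT replicate 2 and 193, 284 and 232 without SET2 deletion replicates 1, 2 and 3. The split was 731 higher and 213 lower without centring and 655 and 499 with quantile normalization, and 145 and 626 with both channels well above background. Without centring the median change of all windows was 0.10 for the ratio and 0.13 for Flag. The Flag count of 1343 (722 and 621) was 582 (405 and 177) after scaling by the median absolute deviation, 2349 (1537 and 812) with normexp, 2737 (822 and 1915) after mitochondrial subtraction, 1 with mitochondrial centring, 808 (279 and 529) with both channels well above background and 869 with at least 4 probes. Without centring its split was 1515 and 303. Leaving out a replicate gave 519 to 1293. The Myc count of 16 (12 and 4) was 940 (704 and 236) after scaling by the median absolute deviation and 3 with normexp. It was 29 (15 and 14) with quantile normalization and 131 (121 and 10) with both channels well above background. It was 10 with at least 4 probes and 10 within the scan batch of 2 arrays per strain. It was 23 (22 and 1) with loess, 25 in windows of 0.5 kb, 9 in windows of 2 kb and 0 to 10 without a replicate. Limma called 0 Myc windows after mitochondrial subtraction and in the fit of only the Myc arrays, and centring on mitochondrial probes called 11362, all lower, since Myc ratios there differed by 2.08 between strains. The acetylated H4 count of 5379 was 3194 with loess, 3005 with both channels well above background, 3181 with at least 4 probes, 2762 in windows of 2 kb and 1 with mitochondrial centring, where fewer windows were tested in all but the first and last of these. Leaving out a replicate gave 4127 to 5449. The replicate block gave 950 windows for the ratio, 1468 for Flag, 30 for Myc and 5568 for acetylated H4, and a block by culture 828 for the ratio. Between the strains the numbers pair the samples by the data only for Flag, where the block ended no list call and moved no count by over 1.5 times. Same-numbered Myc (r = −0.19, 0.06 and 0.56, each pair in 1 scan batch) and acetylated H4 arrays (−0.21, −0.11 and −0.14) of the 2 strains did not all correlate best with their own number. Within WT, same-numbered Flag and Myc arrays also deviated together (r = 0.27, 0.34 and 0.20). In the deletion strain they gave r = −0.19, −0.20 and 0.23, so the data do not bear out taking them as 1 culture for the ratio there. The causes of the other shifts were not tested.

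The low-minus-high difference in acetylated H4 (0.51) was 0.41 with normexp, 0.27 with loess, 0.65 after mitochondrial subtraction, 0.65 in the immunoprecipitate channel alone and 0.59 within a scan day, and 0.45 to 0.56 without a replicate. That in the ratio (0.21) was 0.0892 after scaling by the median absolute deviation, 0.0582 with normexp, 0.0175 with loess, 0.15 with quantile normalization, 0.14 after mitochondrial subtraction and 0.18 to 0.24 without a replicate. In Myc (0.01) it was −0.000770 without WT replicate 1, and −0.00684 to 0.0470 over all left-out replicates, the lowest without SET2 deletion replicate 1. Myc differed more after scaling by the median absolute deviation, where Flag differed by 0.16 and the ratio, Flag minus Myc, by 0.0892. The end-minus-interior difference in acetylated H4 (−0.46) was −0.27 with loess, −0.57 after mitochondrial subtraction, −0.32 with both channels well above background, −0.42 within a scan day and −0.48 to −0.43 without a replicate. That in the ratio (−0.19) was −0.27 with normexp, −0.26 with quantile normalization, −0.57 after mitochondrial subtraction, −0.0891 with both channels well above background and −0.22 to −0.15 without a replicate. The correlation of ratio and acetylated H4 changes (0.33) was 0.18 after scaling by the median absolute deviation, 0.24 with normexp, 0.21 after mitochondrial subtraction, 0.24 with both channels well above background and 0.25 to 0.35 without a replicate. For windows within 20 kb of an end, an estimated correlation moved the camera adjusted p to 0.18 for the ratio, 0.18 for Flag and 0.0738 for acetylated H4, and fry gave Myc 0.0416. The input difference at SET2 was −6.94 to −6.90 without a replicate.

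Among named windows, the sign turned in 7 cases. With normexp the chromosome 10 window at 103001 was −0.13 in acetylated H4 and −0.58 in Flag, and the chromosome 12 window at 1048001 was 0.0462 in Myc. With mitochondrial centring the Myc rises at 382001 on chromosome 11, 195001 on chromosome 10, 26001 on chromosome 13 and 1128001 on chromosome 4 were −0.93, −0.95, −1.12 and −1.14. In the other cases the sign held, and 26 of the ratio, 15 of the acetylated H4, 12 of the Flag and 69 of the Myc values were no longer past the threshold.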

Other observations

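All tests in this part were chosen after the data were seen.

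On chromosome 3 the lower acetylated H4 at the right end went together with lower new H3, while on chromosome 5 from 559001 to 570000 acetylated H4 changed by −0.78 and Flag by −0.21, and on chromosome 15 from 1001 to 11000 by −0.73 and −0.19. Chromosome 3 carries the silent mating-type loci near its ends, and whether these windows hold one was not tested, because no annotation of the build was used here.

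Input signal, centred on the array median, differed between the strains outside SET2 as well. Whether the DNA itself differed was not tested. In 1011 nuclear probes outside the SET2 run every SET2 deletion input lay below every WT input by more than 0.5 log2, and in 0 probes of the array the reverse held.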
